A study of Mus musculus with 36 samples.

How the data were processed

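RNA from the left lung of male mice was measured with the nCounter Mouse Fibrosis V2 panel, per the series design text. The table held 760 endogenous, 10 housekeeping, 8 negative control and 6 positive control probes. Wild-type and Lcn2 knockout mice, 8 to 13 weeks old, received 15 weekday intranasal instillations of 50 µl of saline or of 12.5% dust extract from swine barns, per the labels' protocols. Lungs were taken after lavage, 5 h or 72 h after the last instillation, per the labels' protocols. In the third set, knockout mice were studied at 72 h with or without recombinant IL-10, given at 1 µg per 25 g of body weight on the day of the final instillation and 48 h after it, per the labels' protocols. Each of the 12 groups had 3 lungs from independent experiments, and each of the 3 sets of 12 samples filled 1 cartridge, per the series design text. Time after the last instillation and cartridge therefore coincided, and levels were not compared across sets. The design text gave 50 ng of RNA per sample, 18 h of hybridisation and RNA integrity numbers of 7 to 9.

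The authors processed the data with nSolver 4.0, with 8 housekeeping genes (Rplp0, Ppia and Pgk1, with Acad9, Nubp1, Nol7, Mtmr14 and Cnot10) and a count threshold of 50, per the series design text. The deposited values of the 5 h set and the 72 h set were whole counts, tested on the values, although the deposited table was called normalized. The deposited values of the IL-10 set were a housekeeping-normalized signal: dividing each column by 1 constant gave whole counts for 100% of its values, within 0.01 for values under 60 and within 0.1 for all values. Both deposited tables held the same 28224 values, with 0 differences. Genes are named as the probes were. Of 770 gene probes, 717 had 1 symbol in the platform annotation, 0 had several, 53 were not listed there and 7 had a symbol other than the probe name. The accessions of 761 probes were found in the RefSeq gene table, and 754 of these carried the probe's name.

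Columns were compared value by value. In the 5 h set, the column of wild-type saline replicate 13 equalled 1 column of knockout saline in 784 of 784 values. Those of knockout saline replicates 1 and 19 equalled that of knockout dust extract replicate 24 in all 784 values. The 36 columns thus held 33 distinct profiles, and 2 profiles stood under more than 1 group. The 5 columns that carried them were left out, because nothing in the labels told which group they belong to. This left 7 columns at 5 h: 2 of wild-type saline, 3 of wild-type dust extract and 2 of knockout dust extract. No column of knockout saline was left, so its comparisons at 5 h could be made only with the columns as labelled, which are given beside the report's text on them.

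Each set was fitted alone with 1 mean per group, so that its groups shared an estimate of the spread. No term for the experiment a lung came from was fitted. For the count sets, edgeR 4.0.16 (quasi-likelihood test) was used with libraries scaled by the geometric mean of the 8 housekeeping genes. For the IL-10 set, limma 3.58.1 (lmFit and eBayes with a mean-variance trend) was used on log2 of the value plus 1. The plan had named limma for every set, on the premise of normalized values throughout; the whole counts called for edgeR, and limma's counts of genes are given where they differ. Genes were tested where at least 3 samples of a fit reached 50 normalized counts, which kept 604 genes at 5 h, 615 at 72 h and 603 in the IL-10 set. The change of the effect from 5 h to 72 h in wild type was tested on the 19 columns of the first 2 sets and 630 genes. Tests were two-sided, with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. Tables of means and SD use housekeeping-scaled counts.

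The following was set before the data were examined: the comparisons, the filter, the gene lists, the alternatives planned, and the rule for naming genes. In each comparison of dust extract with saline, the rule named up to 8 called genes with the largest rise and up to 6 with the largest fall. In other comparisons it named up to 5 each way, or the 3 genes with the smallest p where none was called. It also named Lcn2 wherever measured and up to 4 members of a described list with the smallest p. Genes named outside it are marked as such.

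Of 23 gene lists, 18 had at least 4 tested members in some comparison and were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. They covered neutrophils and neutrophil attraction, monocytes and macrophages, B cells with plasma cells and follicles, T and NK cells, MHC class II, MHC class I, interferon response, inflammatory cytokines with NF-kB, IL-10 signalling, collagens, matrix remodelling, TGF-beta and BMP signalling, fibroblasts with smooth muscle, endothelium, complement, fatty acid oxidation with PPAR signalling, oxidative stress with iron handling, and the 8 housekeeping genes. The neutrophil list had too few tested members at 5 h and in the IL-10 set. Type 2 immunity, lung epithelium, cell cycle, fat tissue, and blood with muscle had 9, 2, 3, 5 and 1 probes on the panel and were too small to test. Camera sets a list against the rest of a panel that was itself chosen for fibrosis and inflammation. Each call is given with its value under an estimated correlation, and limma's fry tested whether a list moved one way on balance. Of 48 calls by camera over all comparisons, 1 held with an estimated correlation.

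Total counts per sample were 592374 to 758338 at 5 h and 608807 to 878155 at 72 h. In the IL-10 set, the recovered totals were 300516 to 591562. The median standard error of a log2 fold change was 0.19 for wild-type dust extract at 5 h, 0.24 for knockout dust extract at 72 h and 0.16 in the IL-10 set. The tests were run on simulated counts with 200 changed genes, drawn from the means of the real samples. Each gene was drawn independently, so the simulated samples shared no axis like that of the 72 h set, described below. With 604 genes and 3 against 2 samples as for wild type at 5 h, 44% of genes changed 1.5-fold and 86% of genes changed 2-fold were called. For the knockout at 72 h with 615 genes, these shares were 38% and 82%, and for the knockout without IL-10 with 603 genes they were 74% and 96%. False calls made up 4.62%, 3.66% and 3.65% of the calls in these 3 simulations.

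Alternatives were no filter, a filter on the mean, median-ratio, TMM and quantile scaling, no mean-variance trend, and only the groups of a contrast. Others were all sets in 1 fit, a pseudocount of 10, each sample left out, DESeq2 1.42.0, limma for counts and edgeR for the recovered counts. The 72 h set was also fitted with 1 surrogate variable (sva 3.50.0) and with the title's letter as a block. The 5 h columns were also fitted as labelled. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The positive and negative control probes and the 2 housekeeping probes outside the submitters' 8 were not used for scaling. Counts of the named genes were set against the highest of the 8 negative controls of the same sample. A comparison of deposited whole counts with the authors' own normalized values was not made here.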

Results

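The series measured 770 genes of a fibrosis panel in the lungs of wild-type and Lcn2 knockout mice after repeated inhalation of dust extract from swine barns, early after the last dose and after a period of recovery. Lcn2 encodes lipocalin 2, a protein that binds bacterial siderophores and is released by neutrophils and epithelium. The panel carried 0 probes for Lcn2, so the genotype given by the labels could not be checked from the values. Each of the 12 groups had 3 columns by the labels, and 31 of the 36 columns stood under 1 group only. The 5 others, all at 5 h, were identical to a column of another group and were left out. Total counts per sample ran from 592374 to 758338 at 5 h and from 608807 to 878155 at 72 h. In the IL-10 set they ran from 300516, in knockout dust extract with IL-10 replicate 8, to 591562 after the normalization was undone.

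The first comparison asked what dust extract changed in wild-type lungs 5 h after the last instillation. Cxcl10, an interferon-induced chemokine that draws T cells, stood at 71.7 ± 5.98 normalized counts (SD, n = 3) after dust extract and 24.8 ± 2.22 (SD, n = 2) after saline. Its estimated log2 fold change was 1.53 (SE 0.21; adjusted p = 0.0229), but in both saline samples its counts, 22 and 24, did not exceed the highest negative control, so the size of the change is not known. Marco, a scavenger receptor of alveolar macrophages, rose from 338 ± 37.3 to 947 ± 202 (SD; log2 fold change 1.49, SE 0.22, adjusted p = 0.0308). Cybb, the catalytic subunit of the phagocyte NADPH oxidase, rose from 772 ± 0.177 to 1743 ± 120 (SD; log2 fold change 1.17, SE 0.19, adjusted p = 0.0398). Arg1, which encodes the arginine-consuming enzyme of alternatively activated macrophages, fell from 284 ± 38.4 to 43.2 ± 4.82 (SD; log2 fold change -2.72, SE 0.18, adjusted p = 0.000222).

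In all 4 of these genes the 3 dust extract samples lay apart from both saline samples. Over all 604 genes tested, 132 showed such a gap, or 21.9% against a chance share of 20%. edgeR called 3 genes higher and 1 lower, with 55 genes at an unadjusted p under 0.05; limma called 4 and DESeq2 16, and edgeR with only the groups of the contrast 1, which was Cybb (adjusted p = 0.0325). In that fit Cxcl10 and Marco had adjusted p of 0.0575 and 0.0710, and Arg1 did not pass the filter. With the columns as labelled, edgeR called 0 genes, with 39 at an unadjusted p under 0.05. The log2 fold changes were then 1.38 for Cxcl10, 1.56 for Marco, 1.26 for Cybb and -2.25 for Arg1, with adjusted p of 0.668, 0.345, 0.345 and 0.345. That fit put back wild-type saline replicate 13 and also the ambiguous knockout profiles, which enter the shared spread, and the share of each in the loss of the calls was not tested. Each single sample counted as well: without dust extract replicate 5, 2 genes were called, and without any 1 of the other 4 samples 1 was, each time Arg1 (adjusted p = 0.0010 to 0.0034). Where 1 saline sample was left, it was assumed to vary like the other groups.

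**Figure D1:**
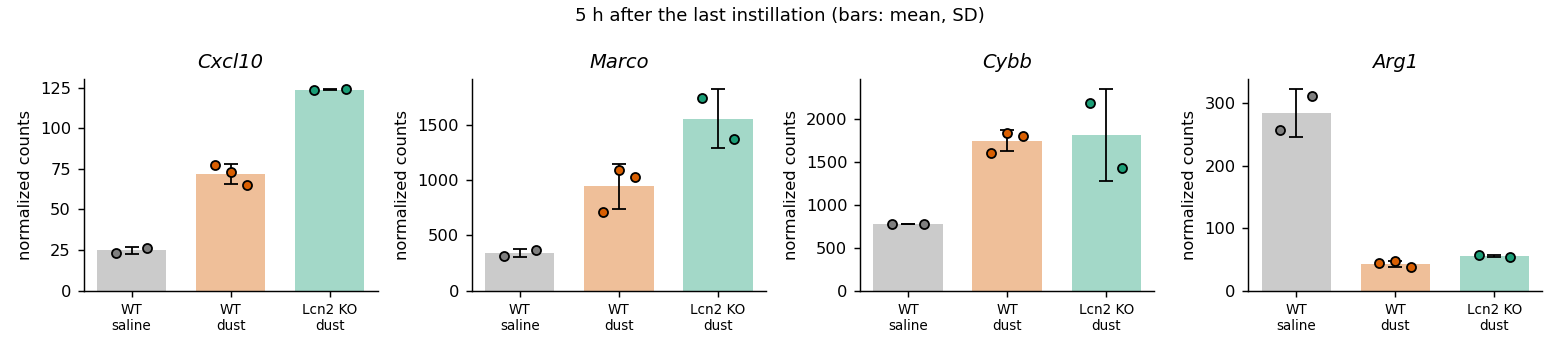
Normalized counts of Cxcl10, Marco, Cybb and Arg1 at 5 h in wild-type saline (n = 2), wild-type dust extract (n = 3) and knockout dust extract (n = 2); bars are means, error bars SD and points samples. The wild-type dust extract samples lie above both saline samples for the first 3 genes and below them for Arg1.

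Among the lists, the monocyte and macrophage genes were higher in 7 of 7 members at 5 h in wild type, with a median log2 fold change of 0.63. Marco led them, followed by Ccr2, the receptor that brings monocytes from the blood (0.80, SE 0.18), the lysosomal macrophage marker Cd68 (0.53, SE 0.13) and Cd84 (0.50, SE 0.16). camera gave an adjusted p of 2.6e-09, and 0.38 with an estimated correlation; adjusted over the list alone, 6 members were called. The MHC class II list, which presents antigen to T helper cells, had a median of 0.46 with 7 of 9 members higher, led by H2-Aa (0.70, SE 0.17). Its adjusted p was 0.00076, and 0.89 with an estimated correlation; adjusted over the list alone, 5 members were called. The endothelium list was lower in 8 of 8 members, with a median of -0.34, led by the VEGF receptor Kdr (-0.46, SE 0.20) and its ligand Vegfa (-0.37, SE 0.18). Its adjusted p was 0.012, and 0.89 with an estimated correlation. fry called 0 of the 17 lists tested.

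Under dust extract at 5 h, the genotypes were compared in 2 knockout and 3 wild-type samples. Cxcl10 stood at 124 ± 0.350 in knockout against 71.7 ± 5.98 in wild type (SD; log2 fold change 0.79, SE 0.17, adjusted p = 0.62). Csf3r, the receptor for the neutrophil growth factor G-CSF, stood at 268 ± 68.6 against 101 ± 11.6 (SD; 1.40, SE 0.32, adjusted p = 0.62). Marco stood at 1561 ± 268 against 947 ± 202 (SD; 0.72, SE 0.21, adjusted p = 0.86). edgeR called 0 of 604 genes, with 19 at an unadjusted p under 0.05; limma called 0 and DESeq2 1, which was Csf3r (adjusted p = 0.0106). camera called 0 lists, and the median over all genes was 0.12 with housekeeping scaling and 0.02 with median-ratio scaling.

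The remaining 5 h comparisons need knockout saline, whose 3 columns all equalled a column of another group. With the columns as labelled, and identical columns within a group counted once, edgeR called 0 genes for dust extract in knockout (55 at an unadjusted p under 0.05). It called 0 for knockout against wild type under saline (5), 0 for the difference between genotypes in the dust extract effect (1), and 0 for the change of the knockout effect from 5 h to 72 h (17). No direction is read from them, since 1 of the profiles was labelled both as knockout saline and as knockout dust extract.

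At 72 h, the comparison asked what was left of the response after recovery in wild type, with 3 samples per group. Mmp9, the gelatinase stored in neutrophil granules, stood at 26.1 ± 5.75 after dust extract and 68.9 ± 23.1 after saline (SD, log2 fold change -1.39, SE 0.33, adjusted p = 0.39). Its counts after dust extract were 22 to 39, against highest negative controls of 20 to 25. Spp1, which encodes the macrophage and matrix protein osteopontin, stood at 2475 ± 155 against 1612 ± 42.9 (SD; 0.62, SE 0.15, adjusted p = 0.39). Gbp3, an interferon-induced GTPase, stood at 143 ± 6.83 against 213 ± 34.7 (SD; -0.58, SE 0.16, adjusted p = 0.58). edgeR called 0 of 615 genes, with 35 at an unadjusted p under 0.05; DESeq2 called 0 (41) and limma 0 (36).

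The median over all genes in this comparison was -0.17 with housekeeping scaling and 0.00 with median-ratio scaling, so list medians are given under both. Interferon response genes had a median of -0.48 (-0.31 by median ratio), led by Gbp3 and Isg15 (-0.56, SE 0.17), and lay 0.31 below all genes; camera's adjusted p was 0.009, and 0.18 with an estimated correlation. Adjusted over the list alone, 2 interferon genes were called, and 0 with median-ratio scaling. B cell genes had a median of -0.50 (-0.30 by median ratio), led by the lymph node homing receptor Ccr7 (-0.87, SE 0.36), and the endothelium list had one of -0.52 (-0.38), led by Kdr (-0.76, SE 0.36). Both had an adjusted p of 0.033, and 0.52 and 0.55 with an estimated correlation. With housekeeping scaling, the endothelium and interferon lists also followed the first principal component of the set, described below. Wild-type dust extract replicates A and E had its lowest scores, at -9.70 and -9.31, while replicate B stood at 3.91. After median-ratio scaling replicates A, E and B stood at -7.74, -5.69 and 4.69, and the interferon list had r = -0.131. Monocyte and macrophage, complement and fatty acid genes then had r of -0.820, -0.744 and -0.716. Monocyte and macrophage genes had a median of 0.19 (0.37 by median ratio), led by the LPS co-receptor Cd14 (0.47, SE 0.26; adjusted p = 0.006, and 0.18 with an estimated correlation), and complement genes one of 0.01, or 0.22 by median ratio (0.033, and 0.18). Matrix remodelling and fatty acid genes were called higher than the panel although their medians were -0.08 and -0.03 (0.033 and 0.015, and 0.42 and 0.27 with an estimated correlation). With median-ratio scaling those medians were 0.11 and 0.16; the mean of the fatty acid list was 0.04 and that of matrix remodelling -0.04. The neutrophil list, with 4 tested members, had a median of -0.80 (-0.63 by median ratio) and an adjusted p of 0.10. fry called 0 lists.

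In knockout lungs at 72 h, Arg1 stood at 46.6 ± 5.07 after dust extract and 120 ± 81.0 after saline (SD, n = 3; log2 fold change -1.37, SE 0.39, adjusted p = 1.00). H2-Eb1, a beta chain of MHC class II, stood at 4046 ± 433 against 2903 ± 201 (SD; 0.48, SE 0.15, adjusted p = 1.00). Cyp1a1, the oxidase induced through the aryl hydrocarbon receptor, stood at 84.5 ± 31.0 against 163 ± 34.4 (SD; -0.96, SE 0.34, adjusted p = 1.00). edgeR called 0 of 615 genes, with 8 at an unadjusted p under 0.05; DESeq2 called 0 (12) and limma 0 (9). The neutrophil list, with 4 tested members, was lower by camera, with a median of -0.85 (adjusted p = 9.3e-05, and 0.43 with an estimated correlation). Mmp9 (-0.88, SE 0.32) and Csf3r (-0.88, SE 0.39) led it. Mmp9 was low after dust extract, with 34 to 43 counts against highest negative controls of 20 to 28. B cell genes had a median of -0.39 (5.2e-05, and 0.44), led by Ms4a1, which encodes CD20 (-0.96, SE 0.47). T and NK cell genes had a median of -0.21 (0.0011, and 0.44), led by the T cell receptor chain Cd3g (-0.42, SE 0.23). Adjusted over the list alone, 0 members of these 3 lists were called, and fry called 0 lists.

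Whether the knockout altered the lung without dust was asked at 72 h under saline. Spp1 stood at 2843 ± 504 in knockout and 1612 ± 42.9 in wild type (SD, n = 3; log2 fold change 0.82, SE 0.15, adjusted p = 0.0822). Eln, the elastic fibre protein elastin, stood at 432 ± 129 against 236 ± 79.6 (SD; 0.87, SE 0.30, adjusted p = 1.00), and Arg1 at 120 ± 81.0 against 58.5 ± 1.25 (SD; 1.04, SE 0.38, adjusted p = 1.00). edgeR called 0 of 615 genes, with 11 at an unadjusted p under 0.05; DESeq2 called 0 (13) and limma 0 (10). With 1 surrogate variable 1 gene was called, and this was Spp1 (0.82, adjusted p = 0.00897); 1 gene was also called without knockout saline replicate E. T and NK cell genes were higher by camera, with a median of 0.26 (adjusted p = 0.0093, and 0.57 with an estimated correlation), led by the cytotoxic granule protease Gzma (0.61, SE 0.28). Matrix remodelling genes had a median of 0.11 (0.0093, and 0.57), led by Spp1, which was its 1 call adjusted over the list alone.

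Under dust extract at 72 h, Derl1, a channel that exports misfolded proteins from the endoplasmic reticulum, stood at 58.4 ± 3.31 in knockout and 35.8 ± 4.55 in wild type (SD, n = 3; log2 fold change 0.71, SE 0.20, adjusted p = 0.55). The MHC class I genes H2-T23 and H2-K1 stood at 2422 ± 171 against 1727 ± 238 (0.49, SE 0.14) and at 9989 ± 613 against 7346 ± 945 (0.44, SE 0.13), each with an adjusted p of 0.55. edgeR called 0 of 615 genes, with 42 at an unadjusted p under 0.05; DESeq2 called 0 (36) and limma 0 (47). The median over all genes was 0.25 with housekeeping scaling and 0.00 with median-ratio scaling. camera and fry called 0 lists; adjusted over the list alone, 3 MHC class I genes and 2 interferon genes were called, and 0 and 0 with median-ratio scaling. The medians of these lists were 0.38 and 0.32, and 0.12 and 0.05 with median-ratio scaling. With housekeeping scaling, both lists followed the first principal component of the set (r = 0.642 and 0.819). On it, wild-type dust extract replicates A and E stood at -9.70 and -9.31 and knockout dust extract replicates B and F at 6.24 and 6.01. The remaining sample of each group lay on the other side, wild-type replicate B at 3.91 and knockout replicate C at -3.03. After median-ratio scaling r was -0.463 for MHC class I genes and -0.131 for the interferon response.

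The dust extract effects of the genotypes at 72 h were set against each other with an interaction term. The change of Spp1 was lower in knockout by -0.93 (SE 0.21; adjusted p = 0.48), that of Pik3r5, a regulatory subunit of PI3 kinase gamma, higher by 1.22 (SE 0.44; 0.89; 2 of 3 knockout saline samples above their highest negative control), and that of the interferon-induced Bst2 higher by 0.57 (SE 0.22; 0.89). The wild-type saline samples enter both this Spp1 value and those given above. edgeR called 0 of 615 genes, with 7 at an unadjusted p under 0.05; DESeq2 called 0 (8) and limma 0 (8). The monocyte and macrophage list was lower in knockout by camera, with a median of -0.31 (adjusted p = 0.043, and 0.37 with an estimated correlation). The fatty acid list had a median of -0.06 (0.027, and 0.37). Matrix remodelling was also called lower, although its median was 0.11 and its mean 0.00 (0.041, and 0.46). All-gene medians were 0.22 with housekeeping and -0.01 with median-ratio scaling, and the matrix remodelling median became -0.14. At an unadjusted p under 0.05, 4 genes were lower in both genotypes, against 0.254 for independent lists, and 0 were higher in both. These lists took the spread of each gene from the same fit, so 0.254 is not a valid reference. Across genes, the log2 fold changes of both genotypes had a Pearson r of 0.23 and a Spearman rho of 0.08, and genes are not independent replicates. Without wild-type dust extract replicate B that r was -0.01, and without knockout dust extract replicate C it was -0.03. Without wild-type saline replicate A it was 0.01, and without knockout saline replicate A it was 0.51.

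The change of the wild-type effect from 5 h to 72 h was tested on effects taken within each cartridge. The effect on Arg1 was higher at 72 h by 2.22 (SE 0.50; adjusted p = 0.27), that on the scavenger and chemokine Cxcl16 lower by -0.57 (SE 0.19; 0.99), and that on the leukocyte GTPase Rac2 lower by -0.91 (SE 0.32; 0.99). edgeR called 0 of 630 genes, with 16 at an unadjusted p under 0.05, and called 1, Arg1, when only the groups of the contrast were fitted (adjusted p = 0.00325). camera called 6 lists, all lower. The interferon response had a median of -0.47 (adjusted p = 0.0079, and 0.083 with an estimated correlation; fry 0.034), led by the ubiquitin-like Isg15 (-0.62, SE 0.22). MHC class II genes had a median of -0.41 (0.0011, and 0.36), MHC class I genes -0.33 (0.049, and 0.58) and monocyte and macrophage genes -0.39 (0.0083, and 0.27). Neutrophil genes had a median of -0.94 (0.02, and 0.47), and collagens, the fibre-forming matrix proteins, -0.69 (0.015, and 0.61), led by Col3a1 (-1.08, SE 0.53). With housekeeping scaling, the collagen, interferon and MHC class I lists followed the first principal component of the 72 h set (r = 0.932, 0.819 and 0.642). Wild-type dust extract replicates A and E were lowest on it, while replicate B stood at 3.91. After median-ratio scaling these r were 0.815, -0.131 and -0.463. The median of all genes was -0.13, and 0.01 with median-ratio scaling.

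In the IL-10 set, knockout lungs without IL-10 answered what dust extract changed at 72 h in the absence of lipocalin 2. Cybb rose from 494 ± 46.6 to 1547 ± 338 normalized counts (SD, n = 3; log2 fold change 1.63, SE 0.18, adjusted p = 0.0002). Ctsd, the lysosomal protease cathepsin D, rose from 6508 ± 337 to 14722 ± 913 (SD; 1.18, SE 0.17, adjusted p = 0.0011). Cd68 rose from 491 ± 55.7 to 989 ± 93.1 (SD; 1.01, SE 0.15, adjusted p = 0.0016), and Hc, which encodes complement component C5, from 2107 ± 177 to 4076 ± 357 (SD; 0.95, SE 0.11, adjusted p = 0.0002). The gelatinase Mmp2 rose by 1.03 (SE 0.20), Ncf1, a cytosolic subunit of the NADPH oxidase, by 1.03 (SE 0.20) and the leukocyte adhesion receptor Cd84 by 0.93 (SE 0.18), each with an adjusted p of 0.0098. The anaphylatoxin receptor C3ar1 rose by 0.90 (SE 0.21; adjusted p = 0.0279).

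limma called 19 of 603 genes, all higher, with 69 at an unadjusted p under 0.05. In all 19 the dust extract samples lay above every saline sample, as 120 of the 603 genes showed a gap one way or the other, or 19.9% against a chance share of 10%. Without dust extract replicate 15, 7 genes were called, and without saline replicate 5, 10 were. C3ar1 lost its call with quantile normalization (adjusted p = 0.0592), and Mmp2 with all sets in 1 fit (0.0737).

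Monocyte and macrophage genes had a median of 0.80 in this comparison, with 3 members called, 5 adjusted over the list alone, and camera's adjusted p at 8.5e-06, or 0.080 with an estimated correlation. Besides Cd68 and Cd84 they included Cd14 (0.87, SE 0.17). MHC class II genes had a median of 0.32 (adjusted p = 0.003, and 0.56), with 0 members called and 4 adjusted over the list alone. Oxidative stress genes had a median of 0.27 (0.0055, and 0.13), with Cybb and Ncf1 called. Matrix remodelling genes had a median of 0.11 (0.017, and 0.56), with fibronectin, Fn1 (0.81, SE 0.11), and Mmp2 called and 3 adjusted over the list alone. The endothelium list was lower, with a median of -0.24 (0.003, and 0.088) and 0 of 7 members called, led by the junction protein Cdh5 (-0.22, SE 0.09). fry called the macrophage, oxidative stress and endothelium lists, with adjusted p of 0.0031, 0.0069 and 0.0069.

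With IL-10, a cytokine that restrains inflammation, the same contrast was made in other knockout mice of the set. Cybb rose by a log2 fold change of 1.84 (SE 0.18; n = 3 per group, adjusted p = 5.1e-05), and Ctsd from 7470 ± 57.8 to 20141 ± 5396 (SD; 1.39, SE 0.17, adjusted p = 0.0003). Ncf1 rose by 1.19 (SE 0.20), the IgG receptor Fcgr4 by 1.16 (SE 0.21), the formyl peptide receptor Fpr1 by 1.13 (SE 0.24), the proton channel Hvcn1 by 1.10 (SE 0.20), Cd84 by 1.09 (SE 0.18) and Cd68 by 1.06 (SE 0.15), with adjusted p from 0.0012 to 0.0105. Vegfa fell from 2894 ± 221 to 1676 ± 651 (SD; -0.86, SE 0.22, adjusted p = 0.0246). The angiopoietin receptor Tek (-0.56, SE 0.12), the Notch regulator Numb (-0.54, SE 0.13) and Kdr (-0.53, SE 0.14) fell with adjusted p of 0.0134, 0.0193 and 0.0246. The BMP inhibitor Smad6 (-0.60, SE 0.18) and the transcription factor Jun (-0.57, SE 0.17) fell at 0.0499 and 0.0489, and lost the call with no filter (0.0524 and 0.0506).

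limma called 69 of 603 genes, 47 higher and 22 lower, with 171 at an unadjusted p under 0.05. In 67 of the 69 the groups did not overlap, as in 181 of all 603 genes, or 30.0% against a chance share of 10%. The split moved with the scaling: median-ratio scaling called 44 higher and 12 lower, and TMM scaling 43 and 10. With another test, edgeR on the recovered counts, it was 50 and 14. With only the groups of the contrast 31 genes were called, of which 24 were higher, and with all sets in 1 fit 38, of which 37 were higher. Without saline replicate 14, 24 genes were called, without saline replicate 10, 31, and without dust extract replicate 12, 32. In the fit with all sets, Vegfa, Tek, Numb and Kdr were not called (adjusted p = 0.0891, 0.271, 0.308 and 0.332).

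**Figure D2:**
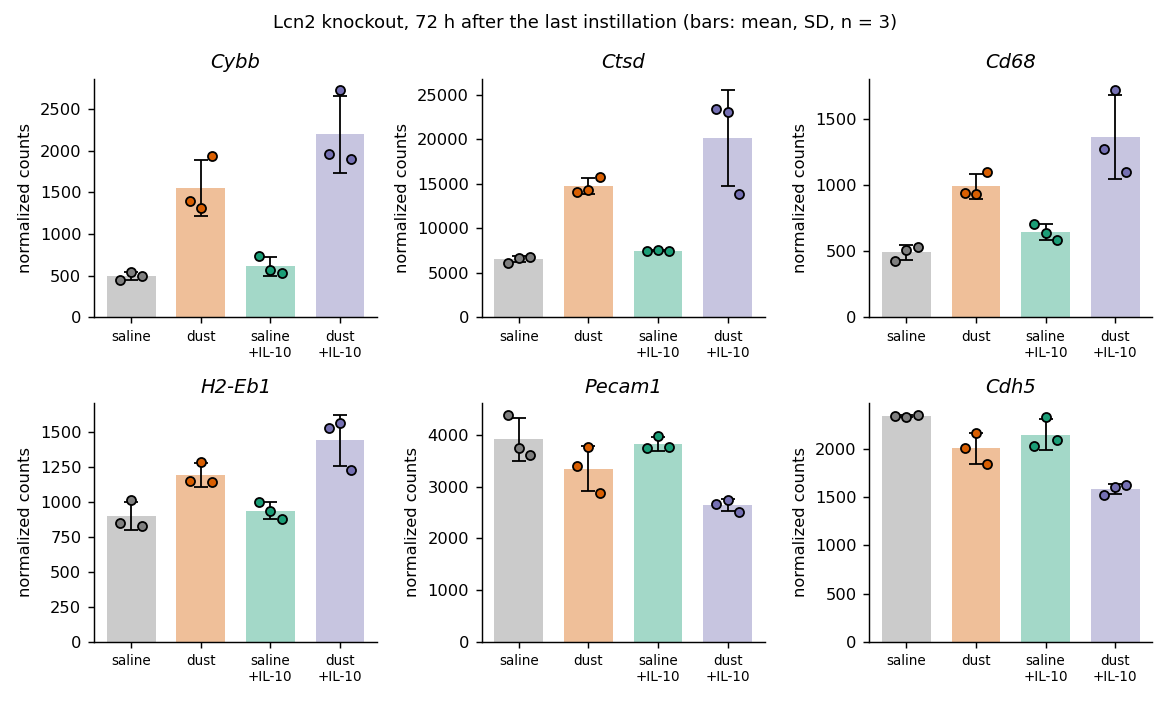
Normalized counts of Cybb, Ctsd, Cd68, H2-Eb1, Pecam1 and Cdh5 in Lcn2 knockout lungs of the IL-10 set, after saline or dust extract, without or with IL-10 (n = 3 per group); bars are means, error bars SD and points samples. With IL-10, the 3 dust extract samples lie above all saline samples for the first 4 genes and below them for Pecam1 and Cdh5.

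In knockout mice given IL-10, the endothelium list was lower after dust extract than after saline. It had a median of -0.53, with 5 of 7 members called, 6 adjusted over the list alone and 0 higher. Besides Tek and Kdr the calls included Pecam1, the adhesion molecule of endothelial junctions (-0.53, SE 0.11), and Cdh5 (-0.44, SE 0.09). camera's adjusted p was 0.00019, and 0.065 with an estimated correlation. MHC class II genes had a median of 0.64 with 6 of 9 members called and 8 adjusted over the list alone (1.2e-05, and 0.19), led by H2-Eb1 (0.61, SE 0.12) and the peptide-loading chain H2-DMa (0.81, SE 0.18). Monocyte and macrophage genes had a median of 0.74 with 3 called and 4 adjusted over the list alone (0.00048, and 0.14). Oxidative stress genes had a median of 0.14 with 3 called (0.013, and 0.18), MHC class I genes 0.40 with 0 called and 4 adjusted over the list alone (0.013, and 0.45), and fatty acid genes 0.16 with 4 called (0.046, and 0.36), led by the fatty acid binding protein Fabp4 (0.99, SE 0.17). fry called 7 lists, these 6 and TGF-beta with BMP signalling.

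The other lists were not called by camera in this contrast. IL-10 signalling genes had a median of 0.47 (adjusted p = 0.42), B cell genes 0.28 (0.42), matrix remodelling genes 0.11 (0.42), T and NK cell genes 0.10 (0.72), collagens 0.02 (0.70) and fibroblast genes 0.01 (0.91). TGF-beta and BMP genes had a median of -0.25 (0.42; fry 0.044), complement genes -0.17 (0.91), interferon response genes -0.07 (0.55), inflammatory cytokine genes -0.04 (0.91) and the 8 housekeeping genes -0.05 (0.91).

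**Figure D3:**
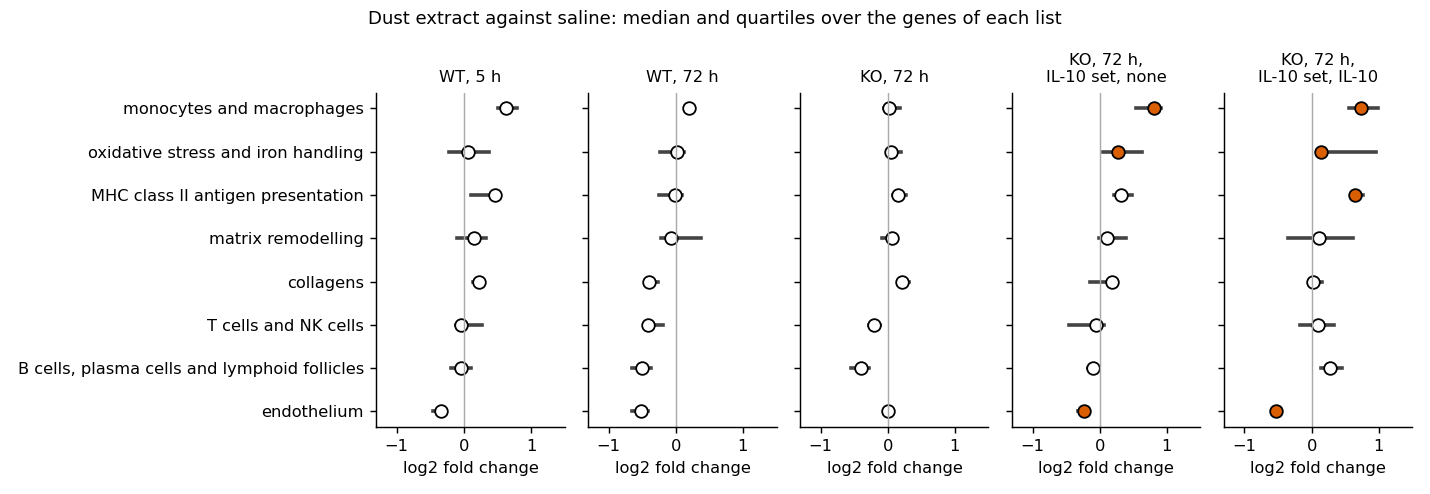
Log2 fold change of dust extract against saline for 8 gene lists in 5 comparisons; dots are medians over the list's genes, lines quartiles, and filled dots lists with fry's adjusted p under 0.05. Monocyte and macrophage genes have medians of 0.63 in wild type at 5 h, 0.80 in knockout without IL-10 and 0.74 with IL-10, and the endothelium list has medians of -0.34, -0.24 and -0.53; in the 72 h set these medians are 0.19 and -0.52 in wild type and 0.02 and 0.01 in knockout.

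Whether IL-10 altered the dust extract effect was tested as the difference between these contrasts, since 69 genes against 19 is not itself a test. The DNA sensor Aim2 had a difference of 0.76 (SE 0.25; adjusted p = 0.99), the endothelial growth factor Pdgfb one of -0.44 (SE 0.17; 0.99) and the phosphodiesterase Pde2a one of 0.72 (SE 0.27; 0.99). limma called 0 of 603 genes, with 9 at an unadjusted p under 0.05, and edgeR 0 (12). MHC class II genes had a higher effect with IL-10 by camera, with a median difference of 0.32 (adjusted p = 0.00042, and 0.54 with an estimated correlation), and so had MHC class I genes at 0.27 (0.004, and 0.54). B cell genes had a median of 0.28 (0.036, and 0.57), T and NK cell genes 0.27 (0.04, and 0.57), and the endothelium list -0.30 (0.012, and 0.34). fry called 0 lists.

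IL-10 itself was compared with none in knockout lungs under saline. Fn1 stood at 1651 ± 182 with IL-10 and 1272 ± 112 without (SD, n = 3; log2 fold change 0.37, SE 0.11, adjusted p = 1.00). The immediate early gene Egr1 stood at 394 ± 67.4 against 182 ± 148 (SD; 1.38, SE 0.41, 1.00), and the monocyte chemokine Ccl2 at 102 ± 26.9 against 45.2 ± 25.8 (SD; 1.33, SE 0.41, 1.00), with 2 of the 3 samples without IL-10 above their highest negative control. limma called 0 of 603 genes, with 12 at an unadjusted p under 0.05, and edgeR 0 (16); without saline replicate 9 that had no IL-10, limma called 1. By camera, monocyte and macrophage genes were higher with a median of 0.32 (adjusted p = 0.00038, and 0.23 with an estimated correlation), matrix remodelling genes with 0.13 (0.00036, and 0.32), complement genes with 0.18 (0.0096, and 0.32) and inflammatory cytokine genes with 0.13 (0.029, and 0.35). MHC class I genes were lower with -0.23 (0.006, and 0.35). fry called 0 lists.

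Under dust extract, Cdh5 stood at 1587 ± 54.0 with IL-10 and 2011 ± 162 without (SD, n = 3; log2 fold change -0.34, SE 0.09, adjusted p = 0.68). Fn1 stood at 2820 ± 172 against 2225 ± 159 (SD; 0.34, SE 0.11, adjusted p = 0.68). limma called 0 of 603 genes, with 38 at an unadjusted p under 0.05, and edgeR 0 (35); without dust extract replicate 16 that received IL-10, limma called 1. The endothelium list was lower with IL-10 in 7 of 7 members, with a median of -0.31, led by Cdh5, Pecam1 (-0.33, SE 0.11) and Tek (-0.31, SE 0.12). camera's adjusted p was 6.3e-05, and 0.048 with an estimated correlation; fry's was 0.011, and 2 members were called adjusted over the list alone. MHC class II genes were higher, with a median of 0.30 (6.3e-05, and 0.35), and so were monocyte and macrophage genes, with 0.38 (0.0076, and 0.34).

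The knockout dust extract effect at 72 h was measured in both later sets, in different mice on different cartridges. Across 595 genes, the log2 fold changes without IL-10 in the IL-10 set and those of the 72 h set had a Pearson r of 0.23 and a Spearman rho of 0.12, with equal signs in 49.7% of genes. Without knockout saline replicate E that r was -0.03, without knockout dust extract replicate C it was -0.01, and without knockout saline replicate A it was 0.52. Of the 19 genes called in the IL-10 set, 0 were called in the 72 h set, where Cybb had 0.42 (SE 0.24), Ctsd 0.27 (SE 0.16) and Cd68 0.33 (SE 0.17). The difference between the sets was not tested gene by gene. The IL-10 effect under dust extract and the knockout dust extract effect of the 72 h set had a Pearson r of -0.11 and a Spearman rho of 0.00 across 595 genes. It was 0.19 without knockout saline replicate A and 0.07 without knockout dust extract replicate B.

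Within the IL-10 set, the dust extract responses without and with IL-10 shared no sample. Of the 19 genes called without IL-10, 17 were also among the 47 higher with IL-10, against 1.48 for independent lists. Cybb, Ctsd and Cd68 were among them. Both lists took the spread of each gene from the same fit, which favours the same genes in both, so 1.48 is not a valid reference. Without dust extract replicate 15 that had no IL-10, 7 were shared, and without saline replicate 5 that had none, 8. Across 603 genes, the log2 fold changes had a Pearson r of 0.76 and a Spearman rho of 0.70. The wild-type effect at 5 h and the knockout effect without IL-10 had a Pearson r of 0.57 and a Spearman rho of 0.51 across 591 genes. At an unadjusted p under 0.05, 25 genes were higher in both, against 3.11 for independent lists, although genes are not independent replicates. Cybb was called in both.

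In the 72 h set, the first principal component held 57.3% of the variance, and 22.3% of it lay between groups. In the IL-10 set it held 38.6%, of which 89.0% lay between groups. Genes with the closest relation to the 72 h component, chosen after their values were seen, were the junction protein Ctnnd1, the receptor Tgfbr2 and the acetyltransferase Crebbp on one side (r = 0.99). On the other lay Ppia, Uqcrh and Psmb7, which serve protein folding, respiration and protein breakdown (r = -0.92, -0.92 and -0.91). Ppia is 1 of the 8 genes used for scaling, and of these the ribosomal protein Rplp0 had -0.83, Pgk1 -0.52 and Nol7 -0.52. The others, Mtmr14, Acad9, Nubp1 and Cnot10, lay on the positive side (0.70, 0.68, 0.61 and 0.54). As a list, the 8 had r = -0.434.

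Of 20 measures related to this component over the 12 samples, the endothelium list had r = 0.951 (rho 0.958, permutation p = 1e-05, rounded and the smallest possible, adjusted p = 1e-04, r = 0.927 without the 2 farthest samples). The interferon response list had r = 0.819 (rho 0.860, permutation p = 0.00209, adjusted p = 0.00697, r = 0.652 without the 2 farthest). The collagen list had r = 0.932 (rho 0.944, permutation p = 1e-05, again the smallest possible, adjusted p = 1e-04, r = 0.888 without the 2 farthest), and MHC class I genes r = 0.642 (rho 0.629, permutation p = 0.0180, adjusted p = 0.0378, r = 0.315 without the 2 farthest). T and NK cell genes had r = 0.248 (rho 0.196, permutation p = 0.430, adjusted p = 0.561, r = 0.0131 without the 2 farthest). The share of the total taken by the housekeeping genes had r = -0.937 (rho -0.930, permutation p = 6e-05, adjusted p = 0.0003, r = -0.893 without the 2 farthest). The component was built from the lists' own genes, scaled by the housekeeping genes. The permutation p-values of the lists are therefore not evidence of a separate relation. That of the housekeeping share is none either, since the share rests on the same housekeeping mean that scaled the values. TGF-beta and BMP genes followed the component about as closely as the endothelium list (r = 0.947, and 0.849 after median-ratio scaling). IL-10 signalling genes had r = 0.876, and 0.539 after median-ratio scaling. After median-ratio scaling, r was 0.900 for the endothelium list, 0.815 for collagens, -0.131 for the interferon response, -0.463 for MHC class I genes and -0.374 for T and NK cell genes.

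**Figure D4:**
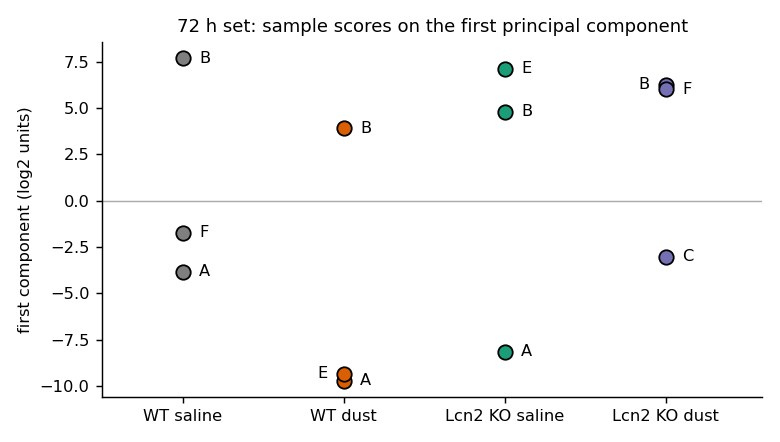
Score on the first principal component for each sample of the 72 h set, by group (n = 3), with the letter of the sample's title. Each of the 4 groups has samples on both sides of 0.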

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

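Of 971 alternatives for named genes, 885 kept the side of the threshold, 81 lost it, 5 gained it and 0 changed direction. The 885 include genes named in comparisons without a call that stayed uncalled, and only called genes could lose it. The 885 therefore do not measure how stable the calls were. Of 339 alternatives for counts and correlations, 284 stayed the same, 49 moved and 6 changed sign. A count stayed the same within 1.5 times, and also where it was 0 both times. A correlation did if it moved by less than the SD of its values with 1 sample left out. Where not stated otherwise, the cause was not tested. A lone sample left in a group was assumed to vary like the other groups. At 72 h, 82% of 2-fold and 38% of 1.5-fold changes were called in simulation, which kept the depth of the real samples. That simulation changed 200 of 615 genes, which eases the adjusted threshold, and drew each gene independently, without the axis of the real samples. Its shares can therefore exceed those of the real comparison. Another pseudocount does not apply to the count sets, and the other deposited table is identical.

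Wild-type dust extract at 5 h called 4 genes, 1 with only the groups of the contrast, 16 with DESeq2, 0 with columns as labelled, and 1 to 2 with 1 sample left out. Knockout against wild type under dust extract at 5 h called 1 with DESeq2. Under saline at 72 h it called 1 with 1 surrogate variable and 0 to 1 with 1 sample left out. Knockout without IL-10 called 7 to 19 with 1 sample left out. With IL-10, 31 were called with only the groups of the contrast, 38 with all sets in 1 fit, and 24 to 86 with 1 sample left out. IL-10 against none called 0 to 1 under saline and 0 to 1 under dust extract with 1 sample left out. The change from 5 h to 72 h called 1 with only the groups of the contrast. Of 48 calls of gene lists, 1 held with an estimated correlation. The overlap between genotypes at 72 h was 4 lower genes at an unadjusted p under 0.05. With the title's letter as a replicate block, each 72 h comparison called 0, as without it; 6 of 11 samples correlated best with their own letter.

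The correlation of knockout effects between sets (0.23) was -0.0337 without knockout saline replicate E, -0.00596 without knockout dust extract replicate C and 0.525 without knockout saline replicate A. That of the IL-10 effect with the dust extract effect (-0.11) was -0.23 without knockout saline replicate E, 0.19 without A and 0.07 without dust extract replicate B. That of the genotypes at 72 h (0.23) was -0.0324 without knockout dust extract replicate C, -0.0103 without wild-type dust extract replicate B, 0.0119 without wild-type saline replicate A and 0.510 without knockout saline replicate A. With no filter, the correlation between sets was 0.09, that of the IL-10 effect -0.18 and that of the genotypes 0.17. That of the effects without and with IL-10 (0.76) was 0.63 with no filter and 0.67 to 0.78 with 1 sample left out; that of wild type at 5 h with knockout (0.57) was 0.40 and 0.47 to 0.62. The overlap without and with IL-10 was 7 to 22. Dust extract over both IL-10 arms called 54 to 142, and IL-10 over both exposures 0 to 2.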

Other observations

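Averaging the dust extract effect over both IL-10 arms, a comparison chosen after the arms had been seen, put 6 against 6 knockout samples and called 88 of 603 genes with limma, 57 higher and 31 lower. The genes named here were chosen after their values were seen. Lpcat1, which makes surfactant phospholipid in alveolar type II cells, was higher by 0.48 (SE 0.08; adjusted p = 0.000771), and H2-Eb1 by 0.51 (SE 0.08; 0.000943). The cytotoxic protease Gzma was lower by -0.66 (SE 0.17; 0.0224), the Notch ligand Dll1 by -0.67 (SE 0.21; 0.0437), the antioxidant enzyme Prdx6 by -0.60 (SE 0.18; 0.0417) and smooth muscle actin, Acta2, by -0.47 (SE 0.14; 0.0401). edgeR called 86; without dust extract replicate 7 or 15 that had no IL-10, 54 were called, without saline replicate 10 that had IL-10, 56, and without dust extract replicate 16 that had IL-10, 142. The IL-10 effect averaged over both exposures called 0 genes with limma, with 40 at an unadjusted p under 0.05, and 0 (38) with edgeR. Gusb, a housekeeping probe outside the 8 used for scaling and a lysosomal enzyme, was higher by 0.56 in knockout without IL-10 (SE 0.14; adjusted p = 0.038).

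For the 3 patterns that follow, the tests on the letter in the title, on the share of tissue types and on the identical columns were written after the values had been seen, and the others before. The first is the axis that crosses the groups of the 72 h set. With median-ratio scaling its component held 48.4% of the variance, over a bound of 45 set beforehand. It lay over that bound by less than the jackknife SE of 6.85, added after the value was seen. With 1 sample left out it held 44.5 to 51.8%, and the components under both scalings had r = 0.97. These values argue against housekeeping scaling as the whole source of the axis. A part stays open, since the component held 57.3% with housekeeping scaling. Of 11 pairs of same-lettered samples, 9 had a correlation over 0.1 and the median was 0.50, against -0.14 for other letters. These were correlations of deviations from group means, which cancel within a group, so -0.14 is not a separate reference. The 11 pairs also shared samples. All A samples lay on the negative side of the component and all B samples on the positive. The lowest same-letter correlation, of the E samples, was -0.34, and the F pair had -0.30. This argues against the letter as the whole account, while a part shared by the A and B samples stays open. The correlations of the endothelium list and of T and NK cell genes with the component differed by 0.70, between the bounds of 0.5 and 1, and lay on opposite sides with median-ratio scaling (0.900 and -0.374), so a varying share of vessel tissue stays open.

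The second is the knockout response that was called in the IL-10 set and not at 72 h in the other. Its 19 genes had a median of 0.27 there against 0.89, with 16 of 19 higher and a mean difference of 0.20 (SE over samples 0.13), against 0.90 (SE 0.09) in the IL-10 set, where the genes were chosen. The median lay under 0.45, the bound set beforehand, but by less than 2 of the standard errors over samples, so spread between samples stays open although these values lean against it. With 1 surrogate variable 0 of the 19 were called, which by the rule set beforehand counted against the axis. Their median was 0.21, while their median SE went from 0.21 to 0.17, that of the IL-10 set. The variable thus narrowed the error and did not raise the fold. How closely it followed the axis was not measured. Knockout saline replicate A, at -8.15 on the component, had a mean log2 value of these genes, centred on the set, of 0.146. Replicates B and E had -0.127 and -0.133. The axis as the account therefore stays open.

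The third is the set of identical columns at 5 h. The closest other pair of columns differed by a chi-square of 4.35 per degree of freedom, which argues against separate libraries that happened to give equal counts. Which label each shared profile belongs to was left open.

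Regrouping the samples of a comparison gave 10 ways at most for 3 against 3, too few to rank the real one. Knockout without IL-10 called 19 genes against 0 for the highest other grouping, and with IL-10 69 against 1; the real one was the 1 grouping to reach that count. Wild type at 72 h called 0 against 1, knockout at 72 h 0 against 0, knockout against wild type under saline 0 against 1 and under dust extract 0 against 0, and IL-10 against none 0 against 1 under saline and 0 against 3 under dust extract. With 100 draws, the genotype difference at 72 h called 0 against 54, which points to a structure of the samples, and the difference made by IL-10 0 against 1.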
